A study of Mus musculus with 4 samples.

How the data were processed

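Single-nucleus RNA sequencing was performed on cortex of 4 adult female C57BL/6JRj mice, a wild-type inbred strain, at about 12 weeks of age. Per the labels' protocols, 2 mice were not pregnant and 2 were pregnant and taken at embryonic day 13.5. Nuclei were isolated from microdissected tissue on ice with actinomycin D, an inhibitor of transcription, and pelleted through iodixanol, per the labels' protocols. About 8000 nuclei per mouse were targeted on a Chromium X instrument with the 10x GEM-X kit for 3' ends, and the pooled libraries were read on an Element AVITI24 sequencer. The area of cortex that was dissected is not given in the sources used here.

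The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs, 1 per captured RNA molecule) for 33696 genes and for the barcodes that the authors' cell calling kept. Cell Ranger 10.0.0 and the mouse genome build GRCm39 are named per the submitters' processing notes, and the file headers carry the same software version. The chemistry is built to read the 3' end of polyadenylated RNA, and counts were not scaled to transcript length. Genes are named by the symbols that the files pair with Ensembl identifiers. The reference used here for other purposes was of an earlier build, so no coordinates are given. Haemoglobin alpha genes are near-identical copies, so the split of counts between Hba-a1 and its copy is uncertain.

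The 4 matrices held 26816 barcodes and 423916014 UMIs. Nuclei with fewer than 500 detected genes or more than 5% mitochondrial UMIs were left out, which kept 26350. Doublets were scored in each library against simulated doublets, 2 per nucleus, by the share of simulated profiles among 60 neighbours, and the top 5% of each library was left out. The final set held 25033 nuclei. In a check with 342 simulated doublets hidden in non-pregnant replicate 1, the score marked 31.3% of them and 3.68% of real nuclei, so doublets were only partly removed. Matrices without the empty droplets were used, so free RNA in the suspension was not subtracted.

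Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes gave 40 principal components. Leiden clustering (resolution 1, 20 neighbours) gave 42 clusters, and resolution 2 gave 60. Clusters were named from 35 marker lists fixed before the data were examined. Each name means that a cluster resembles the cell type by its markers. The names IT, ET, NP and CT stand for intratelencephalic, extratelencephalic, near-projecting and corticothalamic neurons, which are classes of excitatory cortical neurons defined by where their axons go. The score thresholds for naming were set after the clusters had been seen. A name needed at least 3 detected markers. Clusters with more than 35% of nuclei marked as doublets, with leading genes of another class, or with a low median UMI count for their library and no markers of the name among their leading genes stayed unnamed. Clusters of 50 or more nuclei whose share was below 0.2% in both libraries of one group were also kept out of the named types, and their shares per library are reported.

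Raw UMI counts were summed over the nuclei of each library, over all excitatory and all inhibitory neurons, and over each of the 15 cell types with at least 50 nuclei in every library. Each sum was tested with edgeR's quasi-likelihood test with robust estimation, TMM normalisation and the filterByExpr filter, with a minimum count of 10. Benjamini-Hochberg adjustment was made within each unit, and genes with adjusted p below 0.05 were called. Numbers of nuclei per named type were tested with edgeR's quasi-likelihood test against all kept nuclei of the library, adjusted over 21 types. Gene lists, 31 in all and fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 on log2 CPM (prior count 2), a gene's count scaled to the normalised size of its library, where at least 5 members were tested. The 147 list tests were adjusted together. Differences of the pregnancy effect between excitatory neurons and other classes were tested with edgeR as an interaction with the animal as a block. Values are given as log2 fold change of pregnant over non-pregnant with its standard error (SE), or as mean CPM with the standard deviation (SD).

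Genes are named by a rule fixed before the data were examined. In the whole library it takes the 10 genes that rose and the 10 that fell with the smallest p among called genes whose groups do not overlap. In each cell type it takes the 2 that rose and the 2 that fell. It adds up to 10 genes called in the most cell types, up to 4 members of each list described, and the levels of Prlr, Esr1, Pgr, Oxtr, Nr3c1 and Xist. Predicted genes are counted and not named, and some genes that the rule takes are not reported here.

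The tests were tried on simulated counts drawn from the real means, with 50 genes changed at each fold. Genes were drawn independently with the spread that edgeR's trend gives for their level. Spread particular to a gene and shifts shared by the genes of a library were left out. The numbers of false calls below therefore do not bound those in the real data. For the whole library (20902 genes), 21 of 50 genes changed 1.5-fold were recovered, 38 at 2-fold, 47 at 3-fold and 50 at 4-fold, with 3 false calls. For L2/3 IT neurons (16719 genes) the recovered numbers were 15, 35, 43 and 50, with 13 false calls. For astrocytes (10511 genes) they were 5, 22, 41 and 48, with 1 false call. For oligodendrocytes (10117 genes) they were 11, 31, 40 and 50, with 5 false calls. For microglia (9549 genes) they were 12, 25, 45 and 47, with 5 false calls. For Lamp5 neurons (9025 genes) they were 13, 33, 40 and 49, with 11 false calls. For cell shares, 50 simulated tables of 21 types gave a call for 60% of types changed 2-fold and for 0.737% of unchanged types.

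Each group held 2 animals, so p-values measure the spread between 2 libraries per group. An exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333, so calls rest on the model's spread shared across genes. The 2 libraries of a group differed by more than sampling noise, with chi-square per degree of freedom of 25.9 for the non-pregnant pair and 15.7 for the pregnant pair. Alternatives were DESeq2 and its size factors, no filter on low counts, a replicate block, leaving out each library, no doublet filter, stricter filters (at least 1000 genes and at most 1% mitochondrial UMIs), resolution 2, adjustment over all cell types, equal nuclei per cell type, TMM over cell types, an estimated correlation and limma's fry. Equal nuclei per fine cluster, sums without some clusters, other denominators of shares, counting clusters of one group with the nearest type and a list test of the difference between classes were added after seeing the data. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.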

Results

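Nuclei of the cortex were profiled in 2 non-pregnant and 2 pregnant mice to ask how the cells of the adult cortex differ in mid-gestation. Non-pregnant replicate 1 held 6932 barcodes with 97875766 UMIs (median 13187.5 per barcode) and 3940 genes per barcode at the median. Non-pregnant replicate 2 was the deepest, with 6357 barcodes, 116860425 UMIs (median 17723) and 4527 genes. Pregnant replicate 1 held 6680 barcodes, 107434942 UMIs (median 14330.5) and 4088 genes, and pregnant replicate 2 held 6847 barcodes, 101744881 UMIs (median 13444) and 4102 genes. After filtering, 6503 and 5949 non-pregnant and 6228 and 6353 pregnant nuclei remained.

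The make-up of the cortical samples differed between the groups. Upper-layer L2/3 IT neurons made up 29.7% ± 0.370 of nuclei in non-pregnant and 18.2% ± 2.498 in pregnant libraries (SD, n = 2 each), and L4/5 IT neurons 21.7% ± 0.218 and 14.97% ± 1.01. The deep-layer L5 ET neurons, which project out of the telencephalon, rose from 2.5002% ± 0.683 to 4.25% ± 0.622, and L5/6 NP neurons from 1.34% ± 0.325 to 2.06% ± 0.0177. The neurons of the Car3 or claustrum type fell from 0.260% ± 0.107 to 0.0320% ± 0.0229 and L6b neurons, at the border to the white matter, from 0.259% ± 0.0617 to 0.0559% ± 0.0345. Astrocytes rose from 2.21% ± 0.321 to 3.72% ± 0.277 and endothelial cells, which line blood vessels, from 0.290% ± 0.0410 to 0.685% ± 0.145, while microglia, the resident immune cells, fell from 5.53% ± 0.166 to 3.84% ± 0.553.

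These 9 of 21 named types passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 ratios of pregnant over non-pregnant were -0.70 (SE 0.178, adjusted p = 0.00216) for L2/3 IT, -0.54 (SE 0.179, 0.0140) for L4/5 IT, 0.76 (SE 0.202, 0.00216) for L5 ET and 0.61 (SE 0.225, 0.0229) for L5/6 NP. They were -2.94 (SE 0.627, adjusted p = 6.07e-04 by edgeR) for the Car3 or claustrum type and -2.17 (SE 0.556, 0.00216) for L6b, on 12 and 20 non-pregnant against 3 and 1 pregnant nuclei of the Car3 or claustrum type and 14 and 18 against 5 and 2 of L6b. Among glia and vessels they were 0.75 (SE 0.206, adjusted p = 0.00245 by edgeR) for astrocytes, 1.24 (SE 0.328, 0.00216) for endothelial cells and -0.52 (SE 0.194, 0.0229) for microglia. The other 12 types, L5 IT, L6 IT, L6 CT, Pvalb, Sst, Vip and Lamp5 neurons, oligodendrocytes, newly formed oligodendrocytes, oligodendrocyte precursors, mural cells and fibroblasts, did not pass. Mural cells came closest, with a log2 ratio of 0.81 (SE 0.410, adjusted p = 0.114 by edgeR).

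Among non-excitatory nuclei alone, a denominator chosen after seeing the data, the log2 ratios were 0.79 for astrocytes, 1.27 for endothelial cells and -0.48 for microglia (adjusted p 2.05e-04, 0.00138 and 0.00478 by edgeR). Leaving out non-pregnant replicate 2 left 5 types called, leaving out pregnant replicate 2 also left 5, and leaving out pregnant replicate 1 left 2, the Car3 or claustrum type and L6b. The L2/3 IT call was lost at resolution 2 (log2 ratio -0.36, adjusted p = 0.132 by edgeR). There a cluster with L2/3 IT as its best marker list stayed unnamed for its leading genes. It held 283 and 525 non-pregnant and 145 and 152 pregnant nuclei. L2/3 IT nuclei went from 1915 and 1783 to 1620 and 1252 in non-pregnant libraries. In pregnant libraries they went from 1026 and 1271 to 1016 and 1231. The L5/6 NP (adjusted p = 0.0777) and microglia (0.103) calls were lost with TMM over cell types in edgeR. The L2/3 IT and L4/5 IT results depend on where the neuronal clusters found almost only in pregnant libraries are counted. With those clusters added to the nearest type by markers, a setting chosen after seeing the data, the log2 ratios were -0.34 for L2/3 IT and -0.24 for L4/5 IT and neither passed (adjusted p 0.138 and 0.353 by edgeR). With those clusters left out of the total, also chosen after seeing the data, L2/3 IT passed (-0.53, adjusted p = 0.0178 by edgeR), while L4/5 IT (-0.36, 0.121) and microglia (-0.35, 0.150) did not. Averaged over the libraries of a group, cluster 0 held the largest part of L2/3 IT nuclei in non-pregnant (48.1%) and cluster 3 in pregnant libraries (41.9%). Pregnant replicate 2 did not follow, with 504 nuclei of cluster 0 and 466 of cluster 3. At resolution 2 the same cluster held the largest part of L2/3 IT nuclei in both groups (41.1% and 27.6%). For L4/5 IT nuclei the largest was on average cluster 4 (37.8%) in non-pregnant and cluster 6 (38.8%) in pregnant libraries. Non-pregnant replicate 1 did not follow, with 449 nuclei of cluster 4 and 479 of cluster 6.

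A group of neuronal clusters was found almost only in pregnant libraries and was kept out of the named types. Clusters 16, 21, 23 and 33 together held 14 nuclei of non-pregnant replicate 1 (0.215%, Wilson 95% interval 0.128 to 0.361) and 0 of 5949 of non-pregnant replicate 2, where the Wilson interval reaches 0.0645%. They held 766 nuclei of pregnant replicate 1 (12.3%, interval 11.5 to 13.1) and 709 of pregnant replicate 2 (11.2%, 10.4 to 12.0). Their leading genes included Tshz2 and Htr2c in cluster 16, Slc17a6, a vesicular glutamate transporter, in cluster 21, Tshz2 and Nxph2 in cluster 23, and Scnn1a in cluster 33. Cluster 21 stayed without a class for its leading genes. They hold Slc17a6 of the fixed list of thalamic neurons and Sv2c of the Lamp5 list, and no marker of the excitatory lists. The tissue that cluster 21 came from was not tested. An unnamed cluster of low depth (median 1257 UMIs), led by haemoglobin and mitochondrial transcripts, made up 0.861% and 1.09% of non-pregnant and 2.06% and 6.89% of pregnant nuclei. Intervals and limits cover counting error only.

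**Figure D1:**
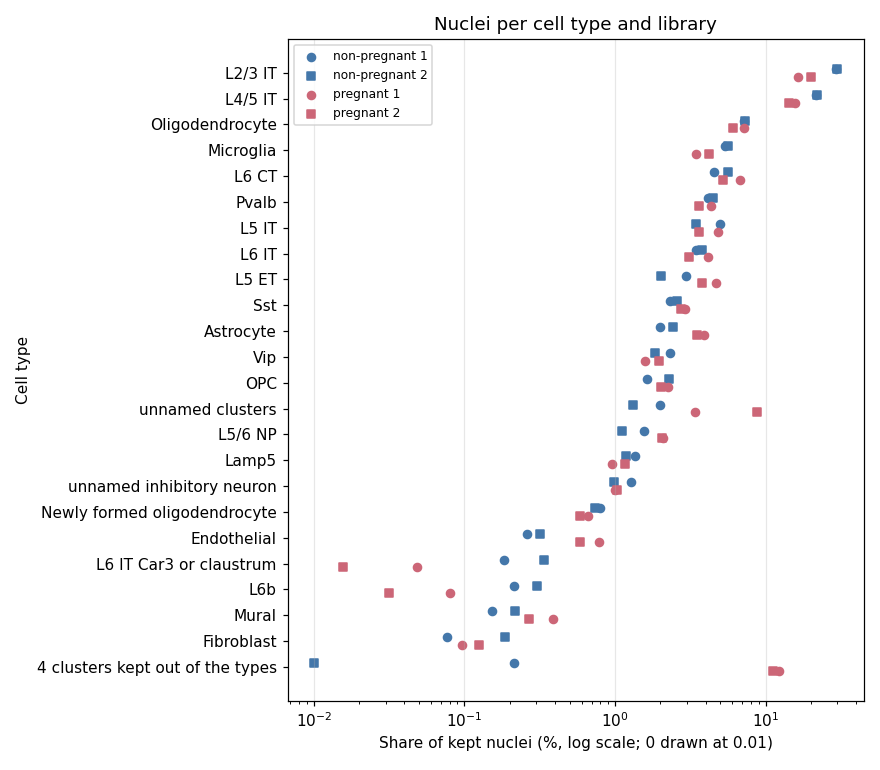
Share of kept nuclei (percent, log scale, with 0 drawn at 0.01) for each cell type, each point 1 library (blue, non-pregnant; red, pregnant; n = 2 per group). L2/3 IT neurons averaged 29.7% in non-pregnant and 18.2% in pregnant libraries, and astrocytes 2.21% and 3.72%. The 4 clusters kept out of the types because they were nearly limited to one group stood at 12.3% and 11.2% in the pregnant libraries.

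In the sum over all nuclei, 143 genes rose and 93 fell in pregnancy among 20902 tested. Htr2c, Htr4, Rnf152, Dpp4 and Zfpm2 are among the leading genes of clusters 16, 21 or 23, which were nearly limited to pregnant libraries. Htr2c, the serotonin 2C receptor, rose from 17.0 ± 2.91 to 62.9 ± 4.95 CPM (SD, n = 2 each; log2 fold change 1.89), and Htr4, another serotonin receptor, from 12.4 ± 1.88 to 30.0 ± 0.482 CPM (1.28). Zfpm2, a cofactor of GATA transcription factors, rose by 1.31 on the log2 scale, Unc13c, which primes synaptic vesicles, by 0.92, and Norad, a noncoding RNA that binds Pumilio proteins, by 1.19. Dpp4, a peptidase, rose by 1.35 and Sntb1, a syntrophin, by 1.56. Among genes that fell were Adam33, a membrane metalloprotease (45.4 ± 2.30 to 20.99 ± 0.362 CPM), and Siae, a sialic acid esterase.

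The smallest p among genes that rose was that of Parm1 (ENSMUSG00000034981), with log2 fold change 1.12 (SE 0.0809) and adjusted p = 0.00116 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It rose from 26.8 ± 0.162 to 58.3 ± 4.91 CPM. Vwc2l (0.84) and Rnf152 (0.97) complete the 10 named genes that rose. Adam33 changed by -1.11 (SE 0.0777, adjusted p = 0.00116 by edgeR), followed by Siae (-0.77), Cbfa2t3 (-0.82), Tspan11 (-0.99), Cpne9 (-0.77), Sdk1 (-0.65), Clmp (-0.58), Fam53b (-0.76) and Tmem40 (-1.25). The 236 called genes include 45 predicted genes. In a setting chosen after seeing the data, the clusters nearly limited to pregnant libraries and all clusters left without a class were taken out. The clusters without a class include the cluster of low depth and those with many nuclei marked as doublets. In that setting 208 genes were called, 159 of them among the 236. The log2 fold changes were then 0.93 for Htr2c, 0.68 for Dpp4, 0.95 for Zfpm2, 1.06 for Htr4 and 0.79 for Rnf152, and all 5 passed. With equal nuclei per cell type 27 genes were called, 24 of them among the 236, a setting that evens out cell make-up and also lowers depth. Of the 20 genes that the rule takes in the whole library, 13 did not pass there, among them Htr2c (0.45), Htr4 (0.44), Dpp4 (0.48), Zfpm2 (0.59), Rnf152 (0.33), Vwc2l (0.47), Unc13c (0.19) and Siae (-0.43). Parm1 (0.60), Sntb1 (1.04) and Adam33 (-0.62) passed there with smaller changes, while Norad (1.22) passed with a change no smaller. Parm1 is on the fixed marker list of L5 ET neurons, whose share was higher in pregnancy. Vwc2l and Sntb1 are among the leading genes of the L5/6 NP cluster, and Adam33 is among those of cluster 4 of the L4/5 IT type. Leaving out non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 and pregnant replicate 2 in turn gave 1927, 1389, 0 and 6 called genes, and DESeq2 gave 544.

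Receptors for hormones of pregnancy were measured at low to moderate levels and did not pass the test in the whole library. Prlr, the prolactin receptor, stood at 2.07 ± 0.701 CPM in non-pregnant and 2.78 ± 0.550 CPM in pregnant libraries (SD, n = 2 each; adjusted p = 0.555 by edgeR). Esr1, an oestrogen receptor, stood at 3.12 ± 0.313 and 3.93 ± 0.584 CPM (adjusted p = 0.432 by edgeR), and Pgr, the progesterone receptor, at 58.8 ± 3.93 and 67.2 ± 2.93 CPM (0.312). Oxtr, the oxytocin receptor, stood at 0.412 ± 0.114 and 0.449 ± 0.0804 CPM (adjusted p = 0.911 by edgeR) and Nr3c1, the glucocorticoid receptor, at 202.0 ± 0.821 and 211 ± 26.0 CPM (0.854). Xist, expressed from the inactive X chromosome, stood at 1109 ± 47.6 and 1052 ± 28.5 CPM (adjusted p = 0.825 by edgeR).

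Within cell types, L5 ET, L5/6 NP, L5 IT and L6 CT neurons had the most called genes with all 4 libraries, an order that depends on the libraries used. In L5 ET neurons 226 genes rose and 128 fell, in L5/6 NP neurons 151 and 72, in L5 IT neurons 97 and 76 and in L6 CT neurons 92 and 30, while in L6 IT neurons 40 rose and 18 fell. Without non-pregnant replicate 1, 1319 genes were called in L2/3 IT and 981 in L4/5 IT neurons, against 745 in L5 ET neurons. In L5/6 NP neurons Egfem1 rose from 24.6 ± 2.77 to 351 ± 29.3 CPM (SD, n = 2 each; log2 fold change 3.82) and Zfpm2 from 58.4 ± 14.3 to 284 ± 18.8 CPM (2.26), while Oprm1, the mu-opioid receptor, fell from 71.7 ± 11.9 to 22.6 ± 4.96 CPM (-1.66) and Arhgap15 changed by -1.80. In L5 IT neurons Tshz2, a zinc finger transcription factor, rose from 3.78 ± 1.93 to 96.9 ± 1.80 CPM (4.64) and Parm1 by 2.09, while Rxfp2, a relaxin-family peptide receptor, changed by -1.27 and Wwc1 by -0.98. Tshz2 and Zfpm2 are also among the leading genes of cluster 23, which was nearly limited to pregnant libraries. No label separates the dissected area from the condition, so a difference in area stays open for the genes called within excitatory types.

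In L5 ET neurons Zfpm2 (log2 fold change 1.40) and Plcxd3 (1.44) rose, and Lgr5, an R-spondin receptor (-1.42), and Arhgap15, a Rac GTPase activator (-1.04), fell. In L6 CT neurons Ikzf2, a zinc finger transcription factor, rose from 10.4 ± 1.87 to 69.3 ± 0.0398 CPM (2.77) and Egfem1 rose by 1.36, while Bcl2, an inhibitor of cell death (-1.10), fell. At resolution 2 the L6 CT nuclei were on average mostly of cluster 14 in non-pregnant (70.2%) and of cluster 16 in pregnant libraries (65.2%). Non-pregnant replicate 1 had 162 nuclei of cluster 14 and 133 of cluster 16, and non-pregnant replicate 2 had 288 and 49. With equal nuclei per fine cluster, a setting chosen after seeing the data, 92 genes were called in L6 CT neurons, 50 of them among the 122, and Ikzf2 (2.22), Egfem1 (0.95) and Bcl2 (-0.89) passed. In L6 IT neurons Inpp4b (1.59) and Tox (1.12) rose, and Slit2, an axon guidance ligand (-0.68), and Shc3 (-0.72) fell. The adjusted p of these genes in edgeR's quasi-likelihood test ranged from 5.65e-21 for Egfem1 in L5/6 NP neurons to 0.0167 for Shc3 in L6 IT neurons. Counts with non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 and pregnant replicate 2 left out were 745, 862, 255 and 211 for L5 ET, 261, 142, 153 and 166 for L5/6 NP, and 578, 223, 31 and 88 for L5 IT. In the same order they were 887, 497, 10 and 9 for L6 CT and 427, 158, 10 and 49 for L6 IT. DESeq2 called 178 genes in L5 ET, 71 in L5/6 NP and 90 in L5 IT neurons.

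Upper-layer neurons had few called genes with all 4 libraries although they were the most numerous. In L2/3 IT neurons 6 genes rose and 7 fell, among them Norad (log2 fold change 1.35), Inf2, an actin-regulating formin (-0.98), and Crispld1 (-0.75), and the haemoglobin gene Hbb-bs rose from 0.961 ± 0.224 to 8.55 ± 1.23 CPM (SD, n = 2 each). In L4/5 IT neurons the 2 called genes, Tshz2 (17.6 ± 2.31 to 45.5 ± 3.72 CPM) and Norad (14.7 ± 1.57 to 32.9 ± 0.892 CPM), both rose. With equal nuclei per fine cluster, a setting chosen after seeing the data, Inf2 stood at -0.57 and did not pass (adjusted p = 0.131 by edgeR), and Tshz2 in L4/5 IT neurons stood at 0.85 against 1.37 with all nuclei. Without the doublet filter neither Inf2 nor Crispld1 passed in L2/3 IT neurons. Tshz2 is also among the leading genes of the clusters nearly limited to pregnant libraries. The adjusted p was 0.00666 for Hbb-bs and 0.0168 for Norad in L2/3 IT, and 0.0124 for Tshz2 in L4/5 IT, by edgeR. With non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 or pregnant replicate 2 left out, 1319, 552, 0 and 0 genes were called in L2/3 IT and 981, 509, 0 and 0 in L4/5 IT neurons. Over excitatory neurons outside the clusters nearly limited to pregnant libraries, 128 genes rose and 56 fell. That count also depended strongly on the libraries used. The L2/3 IT nuclei were of clusters 0, 1 and 3 and the L4/5 IT nuclei of clusters 4, 6, 9 and 13. Their proportions differed between the groups and also between libraries of a group. DESeq2 called 89 genes in L2/3 IT, 53 in L4/5 IT and 481 in the sum of excitatory neurons.

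Among inhibitory neurons, Pvalb neurons had 59 genes that rose and 24 that fell. Prkg2, a cGMP-dependent kinase, rose in Pvalb neurons from 16.4 ± 1.52 to 45.5 ± 3.78 CPM (SD, n = 2 each; log2 fold change 1.49) and fell in Sst neurons from 127 ± 11.5 to 78.5 ± 10.9 CPM (-0.69). Norad rose in Pvalb neurons (1.38) and in Vip neurons (1.65), while Dgkb (-0.64) and Ankfn1 (-1.51) fell in Pvalb neurons. In Sst neurons, with 11 genes that rose and 5 that fell, Lrrc4c, a synaptic adhesion molecule (0.88), and Pard3b (1.58) rose and Ifit1, an interferon-induced gene (-1.37), fell. In Vip neurons, with 8 and 2, Sntb1 (2.30) rose and Col24a1 (-1.03) and Stac2 (-1.22) fell. Evened out to equal nuclei per fine cluster, which was chosen after seeing the data and lowers depth, Prkg2 passed in Pvalb neurons (1.35) but not in Sst neurons (-0.55, adjusted p = 0.114 by edgeR). Ifit1 in Sst neurons (-1.29) and Sntb1 (1.67), Col24a1 (-0.98) and Stac2 (-1.06) in Vip neurons did not pass there either.

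In Lamp5 neurons 30 genes rose and 8 fell, including Kcnc2, a potassium channel (log2 fold change 0.91), which rose, and Igsf11 (-0.63), which fell. Sox6, a transcription factor of developing interneurons, had 1 UMI in the non-pregnant and 57 in the pregnant Lamp5 sums, a ratio of 69.8 with a 95% counting interval from 12.0 to 2803. The ratio was 32.7 without non-pregnant replicate 2 and 12.4 without non-pregnant replicate 1, where 3 counts were taken for 0. Without the doublet filter its log2 fold change was 1.79 against 5.77. The non-pregnant Lamp5 sums then held 90 and 72 nuclei against 89 and 71, and the pregnant sums held 60 and 74 either way. The size of the Sox6 change therefore depends on few nuclei marked as doublets, which the counting interval does not cover. Vwc2l had 58 UMIs in non-pregnant and 2 in pregnant Lamp5 sums, 23.7-fold lower with an interval from 6.27 to 200.3. Of the 58, 46 came from non-pregnant replicate 2, and without that library the ratio was 10.5. The adjusted p of the genes named in Pvalb, Sst, Vip and Lamp5 neurons ranged from 2.90e-09 for Sox6 to 0.0448 for Col24a1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 or pregnant replicate 2 left out, the counts were 175, 78, 1 and 143 for Pvalb, 106, 39, 40 and 59 for Sst, 55, 8, 11 and 27 for Vip, and 57, 48, 36 and 34 for Lamp5. Over all inhibitory neurons 23 genes rose and 3 fell, with 294, 84, 34 and 169 in that order. DESeq2 called 29 genes in Pvalb, 4 in Sst, 0 in Vip and 1 in Lamp5 neurons.

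In astrocytes 39 genes rose and 16 fell, and transcripts of cholesterol synthesis were lower as a group by camera (p = 0.105 with an estimated correlation). All 22 measured members of that list were lower in pregnancy, with a median log2 fold change of -0.47, and 1 passed over all genes tested, Lss, lanosterol synthase (50.1 ± 3.35 to 23.3 ± 0.425 CPM, SD, n = 2 each). Adjusted over the list alone, 14 members passed. Cyp51 (-0.55), Msmo1 (-0.46) and Nsdhl (-0.53), which act after lanosterol, did not pass over all genes. Acly and Acss2, enzymes that make acetyl-CoA, also fell in astrocytes, from 91.2 ± 6.88 to 45.1 ± 4.98 and from 329 ± 3.74 to 221 ± 36.6 CPM, and were picked out after their values were seen. Lss, Acly and Acss2 did not pass with DESeq2 (log2 fold changes -1.11, -1.02 and -0.58) or with equal nuclei per fine cluster (-1.01, -0.83 and -0.55).

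The list passed limma's camera with adjusted p = 6.44e-09, but not with an estimated correlation (p = 0.105, adjusted p = 0.805). Lss changed by -1.10 (SE 0.263, adjusted p = 0.0137 by edgeR). In excitatory neurons 18 of 23 members had higher values in pregnancy (median 0.25, camera adjusted p = 0.0390, p = 0.581 with an estimated correlation), and without non-pregnant replicate 2 the median was -0.042. A test of the difference per animal between astrocytes and excitatory neurons, chosen after seeing the data, gave a median of -0.72 (camera adjusted p = 1.47e-11, p = 0.106 with an estimated correlation). The differences were -0.53 from inhibitory neurons (adjusted p = 1.01e-07, p = 0.137 with an estimated correlation, camera) and -0.16 from oligodendrocytes (0.0216, p = 0.291). The list's median was also below 0 in oligodendrocytes (-0.17, camera adjusted p = 0.0641) and precursors (-0.19, 0.0628), where it did not pass, so a lower level shared by these glia is not excluded. In microglia 7 of 10 members had higher values (median 0.23, camera adjusted p = 0.358).

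**Figure D2:**
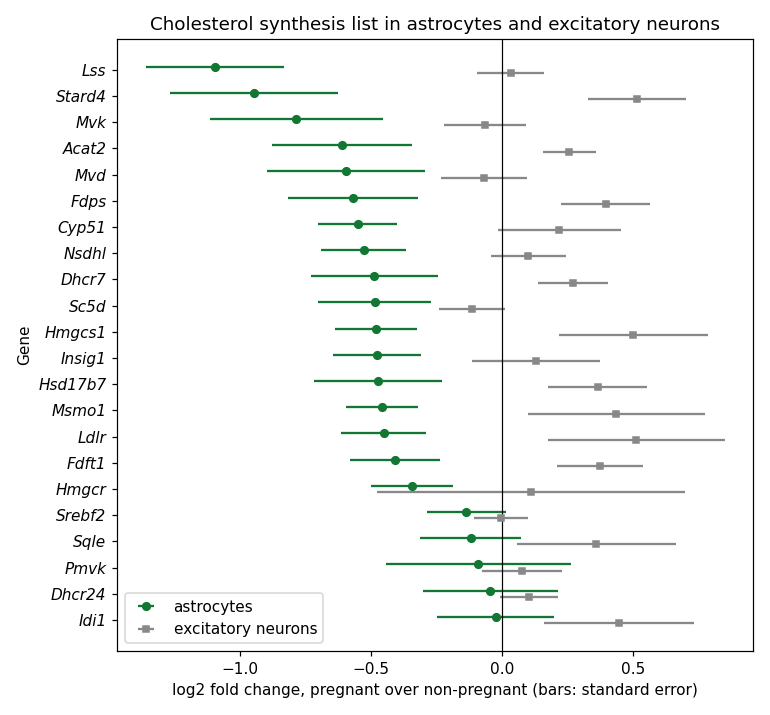
Log2 fold change of pregnant over non-pregnant (points, with bars for the standard error) of the 22 members of the cholesterol synthesis list measured in astrocytes, in astrocytes and in excitatory neurons. All 22 lie below 0 in astrocytes (median -0.47).

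Other named genes in astrocytes were Lgr6 (105 ± 4.00 to 50.6 ± 6.81 CPM, SD, n = 2 each) and Lama3, a laminin chain (260 ± 0.464 to 154 ± 2.02 CPM), which fell, and Snap25, a neuronal release protein (66.5 ± 18.2 to 148 ± 21.5 CPM), which rose. Hba-a1 had 1 UMI in the non-pregnant and 63 in the pregnant astrocyte sums, a ratio of 43.8 with a 95% counting interval from 7.57 to 1755. Of the 63, 46 came from pregnant replicate 2, and without that library the ratio was 23.4 and the gene did not pass. The ratio was 64.6 without pregnant replicate 1. It was 5.62 without non-pregnant replicate 2, where 3 counts were taken for 0. Glutamate receptors passed in astrocytes (13 of 17 higher, median 0.25, camera adjusted p = 0.0241, p = 0.150 with an estimated correlation), with 2 members called, Grm5 (log2 fold change 0.95) and Grm8 (2.48), and 4 adjusted over the list alone. Genes more than 4-fold higher in excitatory neurons had a median log2 fold change of 0.23 in astrocytes. Lgr6 (-1.07), Lama3 (-0.70), Grm5 (1.08) and Grm8 (2.58) did not pass with equal nuclei per fine cluster, nor did any of them or Snap25 with DESeq2. In astrocytes the 55 calls became 85, 25, 36 and 26 without non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 and pregnant replicate 2, 4 with equal nuclei per fine cluster and 1 with DESeq2.

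In microglia 52 genes rose and 2 fell, and the genes that rose include several that neurons use at synapses. Presynaptic release genes passed (18 of 20 higher, median log2 fold change 0.62, camera adjusted p = 1.02e-07, p = 0.136 with an estimated correlation), with 6 called over all genes and 11 adjusted over the list alone, among them Rims2 (1.49), Pclo (1.16) and Cplx1 (1.76). Glutamate receptors were higher in 12 of 12 members (median 0.65, camera adjusted p = 6.53e-06, p = 0.168 with an estimated correlation), with 2 called, Gria2 (0.68) and Grm8 (2.28), and 6 adjusted over the list alone. Dpp10 rose from 102 ± 20.4 to 218 ± 35.3 CPM, Hbb-bs rose from 7.13 ± 2.21 to 42.9 ± 4.57 CPM, and Gab1, a signalling adaptor (340 ± 8.33 to 225 ± 6.17 CPM), and Iars (86.7 ± 5.85 to 44.1 ± 5.94 CPM; SD, n = 2 each) fell. Iars and Grm8 did not pass with equal nuclei per fine cluster. Genes more than 4-fold higher in excitatory neurons than in microglia had a median log2 fold change of 0.51 in microglia, against -0.01 for the other genes.

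GABA-A receptor subunits passed in microglia (7 of 8 higher, median 0.43, camera adjusted p = 0.0139, p = 0.110 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone. In microglia 140, 15, 35 and 26 genes were called without non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 and pregnant replicate 2, and DESeq2 called 1. Lists of homeostatic and activated microglia did not pass.

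In oligodendrocytes, the myelinating cells, 13 genes rose and 2 fell, and in their precursors 11 rose and 6 fell. Camk1d rose in oligodendrocytes from 423 ± 63.8 to 761 ± 110 CPM (SD, n = 2 each), while Chdh, choline dehydrogenase (89.2 ± 2.45 to 45.4 ± 1.14 CPM), and Cldn14, a claudin (97.1 ± 12.6 to 54.6 ± 0.123 CPM), fell. Hsp90aa1, a chaperone, rose in precursors (76.9 ± 14.9 to 156 ± 15.02 CPM), where Rhoq (log2 fold change -0.89) and Creb5 (-0.59) fell. Hbb-bs rose from 4.73 ± 4.32 to 39.7 ± 8.33 CPM in oligodendrocytes and had 3 non-pregnant against 48 pregnant UMIs in precursors, a ratio of 16.9 with a 95% counting interval from 5.43 to 84.6. Without non-pregnant replicate 2, which held 0 of these UMIs, the ratio was 6.36 and the gene did not pass. Cldn14 in oligodendrocytes (log2 fold change -0.74) and Rhoq (-0.66) and Creb5 (-0.64) in precursors did not pass with equal nuclei per fine cluster. The myelin and oligodendrocyte differentiation lists passed in neither.

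Presynaptic release (18 of 21 higher, median log2 fold change 0.55), GABA-A receptor subunits (9 of 9, 0.59) and postsynaptic scaffold genes (13 of 18, 0.31) passed in oligodendrocytes, with 0 members called over all genes and 6, 2 and 0 adjusted over the list alone. Their camera adjusted p were 2.41e-05, 2.39e-04 and 0.0265, against p = 0.0552, p = 0.156 and p = 0.0944 with an estimated correlation. Genes more than 4-fold higher in excitatory neurons had a median log2 fold change of 0.34 in oligodendrocytes and 0.19 in precursors. With non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 or pregnant replicate 2 left out, 338, 35, 48 and 14 genes were called in oligodendrocytes and 22, 6, 25 and 11 in precursors. DESeq2 called 1 and 0.

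Several genes were called in many cell types. Over the 15 tested types 876 different genes were called at least once, and 221 genes, predicted genes left out, in 2 or more types. Hbb-bs rose in 11 types and Hba-a1 in 7, Norad in 9, and Tshz2, mt-Co1, Hunk and Unc13c in 5 each. Egfem1 rose in L5 IT, L5 ET, L5/6 NP and L6 CT neurons (log2 fold changes 1.09, 1.55, 3.82 and 1.36), where Arhgap15 fell (-0.88, -1.04, -1.80 and -0.52). In L6 CT neurons Arhgap15 stood at -0.19 with equal nuclei per fine cluster and did not pass. Hunk, a kinase, rose in L5 IT, L5 ET, L5/6 NP, L6 IT and L6 CT neurons (1.21, 2.05, 2.08, 1.67 and 1.45). Prkg2 rose in 3 types and fell in 1. Tshz2 rose also in astrocytes (2.33), where it did not pass with equal nuclei per fine cluster, and in oligodendrocytes (2.71), with Tshz2 among the leading genes of neuronal clusters that were nearly limited to pregnant libraries.

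Haemoglobin transcripts were higher in pregnant libraries in all 15 tested types, and mitochondrial transcripts were higher in some units. Hbb-bs gave 0.124 to 0.192 UMIs per nucleus in 14 tested types of pregnant libraries and 0.442 in astrocytes, where pregnant replicate 2 alone gave 164 UMIs and pregnant replicate 1 gave 43. In non-pregnant libraries it gave 0.00595 to 0.0302. Mitochondrially encoded transcripts passed camera with higher values in inhibitory neurons (9 of 9 members higher, median log2 fold change 1.62, 9 called), in the whole library (13 of 13, 1.11, 5 called), in excitatory neurons (12 of 12, 1.08, 7 called), in oligodendrocytes (8 of 8, 1.26, 1 called) and in microglia (9 of 9, 1.14, 1 called). With an estimated correlation the p was 0.0391, 0.135, 0.136, 0.109 and 0.154 in that order, and the adjusted p was 0.805 or more, against camera adjusted p from 3.92e-15 in inhibitory neurons to 3.16e-07 in microglia. Adjusted over the list alone, 9, 12, 11, 8 and 7 members passed. mt-Cytb (2.18) and mt-Nd4 (2.13) led in inhibitory neurons and mt-Atp6 (1.20) in the whole library. The samples were nuclei, and the median mitochondrial share of a barcode's UMIs was 0% in both non-pregnant libraries. It was 0.0029% and 0.0058% in the pregnant libraries. Whether these transcripts are RNA carried over from outside the nuclei was not tested, so a change within the cells is not shown.

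The mitochondrial list did not pass in astrocytes (7 of 9 higher, median 0.47, camera adjusted p = 0.155) or in precursors (6 of 8, 0.065, 0.809). The difference of effect per animal in astrocytes, chosen after seeing the data, had a median of -1.15 from inhibitory neurons (camera adjusted p = 8.50e-06, p = 0.212 with an estimated correlation). It was -0.96 from oligodendrocytes (camera adjusted p = 0.00186, p = 0.253 with an estimated correlation) and -0.50 from excitatory neurons (0.0206, p = 0.405).

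**Figure D3:**
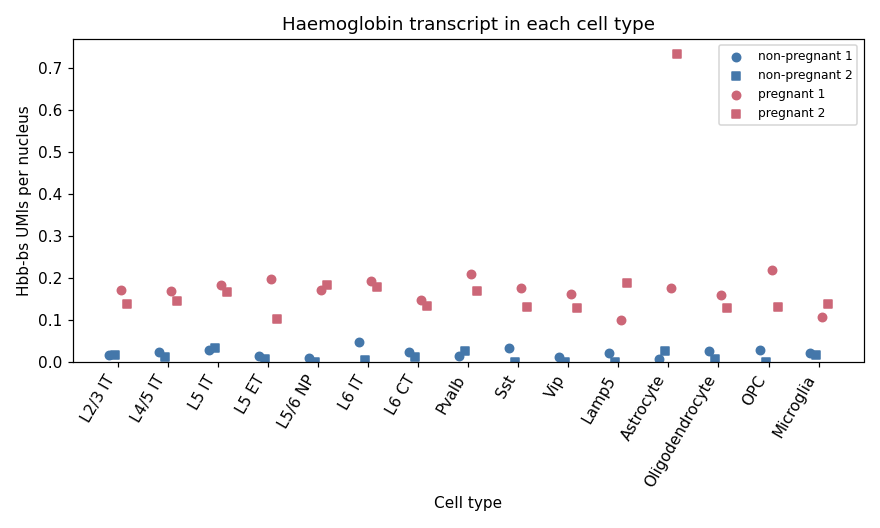
Hbb-bs UMIs per nucleus in each tested cell type, each point 1 library (blue, non-pregnant; red, pregnant; n = 2 per group). Taken over both pregnant libraries the values lie between 0.124 and 0.192 in 14 types and at 0.442 in astrocytes, where pregnant replicate 2 stands apart, and over both non-pregnant libraries between 0.00595 and 0.0302.

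Lists of translation and energy metabolism passed camera with small positive medians, and none held with an estimated correlation (p from 0.163 to 0.646). Cytosolic ribosomal protein genes passed in all 7 units tested, with medians from 0.17 in excitatory neurons (37 of 43 higher) to 0.28 in oligodendrocytes (37 of 43), 0 members called over all genes, and 0 adjusted over the list alone except 1 in microglia. The whole library had 40 of 43 higher. Their camera adjusted p ran from 2.01e-05 to 0.0223, against p from 0.251 to 0.646 with an estimated correlation. In excitatory neurons their median was -0.054 without non-pregnant replicate 2. Nuclear-encoded oxidative phosphorylation passed in astrocytes (28 of 35 higher, median 0.23), oligodendrocytes (29 of 35, 0.25), the whole library (33 of 35, 0.14), microglia (28 of 35, 0.11) and precursors (18 of 30, 0.16). With an estimated correlation its p ran from 0.163 to 0.550, against camera adjusted p from 0.00311 to 0.0480. Of its members only Ndufb9 in astrocytes was called (log2 fold change 1.03), which was also the only member to pass adjusted over the list alone in these 5 units and did not pass over all genes with DESeq2 or equal nuclei per fine cluster. In microglia the median was -0.063 without non-pregnant replicate 2.

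Stress and hormone lists passed camera in some units. Heat shock genes passed in the whole library (15 of 17 higher, median 0.28), microglia (12 of 12, 0.38), oligodendrocytes (9 of 13, 0.38) and precursors (7 of 11, 0.42). With an estimated correlation the p was 0.297, 0.330, 0.404 and 0.175 in that order. Hsp90ab1 was called in microglia (log2 fold change 0.73) and Hsp90aa1 in precursors (1.04), and 0, 3, 4 and 4 members passed adjusted over the list alone. Glucocorticoid and progesterone response genes passed in the whole library (18 of 22 higher, median 0.25) and in astrocytes (14 of 15, 0.28), with 0 called and 2 and 1 adjusted over the list alone. Their p was 0.414 and 0.372 with an estimated correlation. Hif3a stood at 0.71 and Tsc22d3 at 0.50 in the whole library and did not pass. Hif3a, at 129.65 CPM in non-pregnant astrocytes against 2.65 CPM in the whole library, stood at 0.38 within astrocytes, whose share was higher in pregnancy. In the whole library the glucocorticoid list did not pass with equal nuclei per fine cluster (median 0.15, camera adjusted p = 0.131). The camera adjusted p of these 2 lists ran from 0.00694 to 0.0328. Without non-pregnant replicate 2 the glucocorticoid median in the whole library was 0.025 with the test's direction turned.

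Immediate early genes, which neuronal activity induces, passed in the whole library (21 of 22 higher, median 0.90), excitatory neurons (22 of 22, 1.02), inhibitory neurons (20 of 21, 0.63) and oligodendrocytes (13 of 14, 0.36). The camera adjusted p ran from 0.0222 to 0.0446, against p from 0.434 to 0.609 with an estimated correlation. No member was called and 0 passed adjusted over the list alone in these units by edgeR, and Jun stood at 0.45 and Egr1 at 0.59 in the whole library. Without non-pregnant replicate 2 the medians were -0.45, -0.46, -0.37 and -0.16, so that 1 library set the direction. Perineuronal net genes passed in excitatory neurons (11 of 13 higher, median 0.20, camera adjusted p = 0.0231, p = 0.156 with an estimated correlation, 0 called and 0 adjusted over the list alone). Cholesterol synthesis passed in the whole library as well (19 of 23 higher, median 0.21, camera adjusted p = 0.0491, p = 0.599 with an estimated correlation), with a median of -0.017 without non-pregnant replicate 2.

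Of 147 list tests, 37 passed with higher and 1 with lower values by camera, 0 passed with an estimated correlation (smallest adjusted p = 0.805, with 1 unadjusted p under 0.05) and 0 passed by fry (smallest adjusted p = 0.210, with 11 unadjusted). Under equal nuclei per fine cluster 31 of the 38 passed camera. The 7 that did not were the whole library's glucocorticoid, cholesterol and oxidative phosphorylation lists, perineuronal nets in excitatory neurons, ribosomal proteins in astrocytes, and immediate early and postsynaptic scaffold genes in oligodendrocytes. Lists for prolactin and STAT5 signalling, sex steroid receptors, neurosteroid synthesis, the circadian clock, complement, interferon, hypoxia, insulin signalling, thyroid hormone and astrocyte homeostasis passed in no unit tested. Not all of the fixed lists were tested. Those for the blood-brain barrier and angiogenesis were not, since endothelial cells had fewer than 50 nuclei per library. Oxytocin and vasopressin signalling, astrocyte reactivity and the cell cycle had no list test in any unit and stay untested.

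The effect of pregnancy, meaning pregnant against non-pregnant libraries whatever the dissected area, was tested for differences between cell classes. It differed between excitatory and inhibitory neurons for 198 of 19058 genes, 73 of them with a higher log2 fold change in inhibitory neurons. It differed between excitatory neurons and astrocytes for 145 of 18885 genes (51 higher in astrocytes) and between excitatory neurons and oligodendrocytes for 182 of 18637 genes (66 higher in oligodendrocytes). The test was edgeR's quasi-likelihood test of the interaction, with the animal as block. With non-pregnant replicate 1, non-pregnant replicate 2, pregnant replicate 1 or pregnant replicate 2 left out, the counts were 308, 128, 45 and 136 for inhibitory neurons, 207, 58, 61 and 48 for astrocytes, and 330, 121, 59 and 38 for oligodendrocytes. Without the low-count filter the inhibitory count was 569.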

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

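The tests on the clusters nearly limited to pregnant libraries, of free RNA in glia, of depth in oligodendrocytes, astrocytes and precursors, of haemoglobin in each pregnant library and of the other splits of the libraries were chosen only after the results had been seen. The pregnancy effect differed between excitatory and inhibitory neurons for 198 genes, between excitatory neurons and astrocytes for 145 and between excitatory neurons and oligodendrocytes for 182, by edgeR's interaction test. These are differences between groups of cells under the same contrast. For the whole library, the real split of the 4 libraries called 236 genes and the highest of the other splits 0, and 1 of the 3 possible splits reached the real count. That is too few splits for a share under 0.05.

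Clusters 16, 21, 23 and 33, kept out of the named types, are a signal outside the main comparisons. They held 766 nuclei in pregnant replicate 1 and 709 in pregnant replicate 2 against 14 and 0 in the non-pregnant libraries. Other clusters left without a class held 129 and 78 non-pregnant and 211 and 557 pregnant nuclei and are not weighed here. Damage or doublets are argued against for clusters 16, 23 and 33, whose UMIs were 1.10 times their library's median, with at most 2.14% of a cluster marked as doublets, while cluster 21 stood at 0.676 times, so damage may have a part in it, although its 9308 and 9521 UMIs were near the 8910.5 and 9178 of pregnant Vip neurons. Of 13 clusters of 50 or more nuclei assigned to inhibitory or non-neuronal classes, 0 were nearly limited to one group. That count leaves out clusters of mostly doublets such as cluster 26, with oligodendrocyte genes. Cluster 26 had 63 non-pregnant and 150 pregnant nuclei before the doublet filter and 3 and 54 after it. The count cannot decide on a difference in preparation that reaches all cells, because such a difference need not split these classes. Hbb-bs UMIs per nucleus were higher in pregnant libraries in every tested type, with the smallest rise, 5.82-fold, in L5 IT neurons. A difference in preparation therefore stays open. A different part of the cortex in the dissected pieces may account for clusters 16, 21, 23 and 33. The Car3 or claustrum type, which lies in lateral cortex, also differed in share (log2 ratio -2.94). Pregnancy itself stays open and untested, because no label separates the dissected area from the condition.

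Haemoglobin and neuronal transcripts were higher in pregnant glia. A lower depth per nucleus is argued against by the ratio of median UMIs in microglia (0.960) and oligodendrocytes (0.9497), and in astrocytes and precursors, where the ratios were 0.853 and 0.873, by Hbb-bs UMIs per nucleus, which rose 24.2-fold and 14.3-fold without scaling to depth, and by neuronal genes, which without non-pregnant replicate 2 still stood 0.30 and 0.24 above other genes on the log2 scale at depth ratios of 1.05 and 0.997. The size of the astrocyte rise rests largely on pregnant replicate 2, with 0.732 Hbb-bs UMIs per nucleus against 0.176 in pregnant replicate 1. Both lay above the 0.00775 and 0.0276 of the non-pregnant libraries. A change of haemoglobin transcription in each cell type is argued against outside astrocytes, where Hbb-bs per nucleus differed at most 2.20-fold between types in a pregnant library, and stays open in astrocytes, since with them the spread was 7.09-fold in pregnant replicate 2 and 2.20-fold in pregnant replicate 1. Free RNA from other cells is a candidate explanation, since in microglia genes of excitatory neurons had a median log2 fold change 0.52 above that of other genes. The same difference was 0.35 in oligodendrocytes, 0.24 in astrocytes and 0.20 in precursors, and a change within glia stays open for single genes.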

How the results depend on the processing

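Equal nuclei per fine cluster, sums without some clusters, other denominators of shares, clusters of one group counted with the nearest type and the list test of the difference between classes were chosen only after the results had been seen. Counts of called genes were 55 in astrocytes, 13 in L2/3 IT, 2 in L4/5 IT, 354 in L5 ET, 173 in L5 IT, 223 in L5/6 NP, 122 in L6 CT, 58 in L6 IT, 38 in Lamp5, 54 in microglia, 17 in precursors, 15 in oligodendrocytes, 83 in Pvalb, 16 in Sst, 10 in Vip, 184 in excitatory neurons, 26 in inhibitory neurons and 236 in the whole library. Called genes kept their direction under all alternatives run for the 120 named results, and lists kept theirs except in 9 results below. Values are given where a count moved by more than 1.5 times, and unless a sentence says otherwise the cause was not tested.

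With DESeq2, the called genes were 544 in the whole library, 481 in excitatory neurons, 89 in L2/3 IT, 53 in L4/5 IT, 90 in L5 IT, 178 in L5 ET, 71 in L5/6 NP, 29 in Pvalb, 4 in Sst, 0 in Vip, 1 in Lamp5, 1 in astrocytes, 1 in oligodendrocytes, 0 in precursors and 1 in microglia. With DESeq2 size factors in the edgeR fit they were 15 in L4/5 IT. Without a filter on low counts they were 556 in the whole library, 630 in excitatory neurons, 146 in inhibitory neurons, 442 in L2/3 IT, 285 in L4/5 IT, 341 in L5 IT, 677 in L5 ET, 191 in L6 IT, 497 in L6 CT, 146 in Pvalb, 53 in Sst, 22 in Vip, 63 in Lamp5 and 106 in oligodendrocytes, and 569 genes differed in effect between excitatory and inhibitory neurons. Adjusted over all cell types they were 43 in L2/3 IT, 32 in L4/5 IT, 206 in L5 ET, 146 in L5/6 NP, 34 in Sst, 19 in Vip and 35 in oligodendrocytes. This change comes from adjusting the same p-values of all types together, which raised the count in some types and lowered it in others. Without the doublet filter they were 2 in L2/3 IT, 15 in L4/5 IT, 105 in L6 IT, 25 in Sst, 5 in Vip, 8 in oligodendrocytes and 86 in microglia. With the stricter filter of nuclei they were 11 in inhibitory neurons. At resolution 2 they were 20 in L2/3 IT, 15 in L4/5 IT, 96 in L6 IT and 7 in oligodendrocytes. With equal nuclei per cell type 27 genes were called in the whole library. With equal nuclei per fine cluster, which also lowers depth, they were 21 in the whole library, 54 in excitatory neurons, 27 in L2/3 IT, 33 in L4/5 IT, 140 in L5/6 NP, 105 in L6 IT, 41 in Pvalb, 2 in Vip, 4 in astrocytes, 9 in oligodendrocytes and 6 in precursors. Without the clusters nearly limited to one group and all clusters left without a class, 208 genes were called in the whole library, 159 of them among the 236. The clusters without a class include the cluster of low depth and those with many nuclei marked as doublets.

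With each library left out in turn, which leaves 1 library in a group whose spread is taken from the other group, the called genes ran from 25 to 85 in astrocytes, 0 to 1319 in L2/3 IT, 0 to 981 in L4/5 IT, 211 to 862 in L5 ET, 31 to 578 in L5 IT, 142 to 261 in L5/6 NP, 9 to 887 in L6 CT, 10 to 427 in L6 IT, 34 to 57 in Lamp5, 15 to 140 in microglia, 6 to 25 in precursors, 14 to 338 in oligodendrocytes, 1 to 175 in Pvalb, 39 to 106 in Sst, 8 to 55 in Vip, 0 to 1509 in excitatory neurons, 34 to 294 in inhibitory neurons and 0 to 1927 in the whole library. The genes that differed in effect ran from 48 to 207 against astrocytes, 38 to 330 against oligodendrocytes and 45 to 308 against inhibitory neurons. The called lists ran from 19 to 53 and the called shares from 2 to 9. Without pregnant replicate 1, 65 of 119 named results were no longer called, without pregnant replicate 2, 52 of 119, without non-pregnant replicate 2, 23 of 119, and without non-pregnant replicate 1, 5 of 120. Without non-pregnant replicate 2, the deepest library, list medians turned or fell near 0 with the test's direction reversed. For immediate early genes they ran from -0.45 to 2.33 over the libraries left out in the whole library, -0.46 to 2.53 in excitatory neurons, -0.37 to 1.53 in inhibitory neurons and -0.16 to 1.11 in oligodendrocytes. For cholesterol synthesis they ran from -0.017 to 0.34 in the whole library and -0.042 to 0.50 in excitatory neurons. They ran from 0.025 to 0.49 for glucocorticoid and progesterone response in the whole library, -0.054 to 0.44 for ribosomal proteins in excitatory neurons and -0.063 to 0.36 for oxidative phosphorylation in microglia, each lowest without non-pregnant replicate 2. The cholesterol synthesis median in astrocytes ran from -0.59 to -0.31 and stayed called in all 4 of these fits.

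With an estimated correlation 0 of the 38 called lists passed (1 unadjusted p under 0.05), and 0 passed with fry (5 unadjusted). Replicate numbers did not pair the libraries, since the correlation of same-numbered deviations ran from -0.0881 to 0.0519 over 18 units. With the replicate block the called genes were 413 in the whole library, 517 in excitatory neurons, 75 in inhibitory neurons, 43 in L2/3 IT, 7 in L4/5 IT, 90 in L5 IT, 231 in L6 IT, 274 in L6 CT, 136 in Pvalb, 48 in Sst, 26 in Vip, 78 in oligodendrocytes and 95 in microglia, and 9 shares and 39 lists were called. Among shares, the L2/3 IT call was lost at resolution 2, where a mostly non-pregnant cluster with L2/3 IT markers stayed unnamed. The L5/6 NP and microglia calls were lost with TMM over cell types. With the clusters of one group added to the nearest type by markers, the L2/3 IT (log2 ratio -0.34) and L4/5 IT (-0.24) calls were lost, and with those clusters left out of the total, the L4/5 IT (-0.36) and microglia (-0.35) calls. Depth per nucleus was lowest in microglia among the tested types. Its library medians were 2590 to 3284 in microglia and 15562 to 21150 in L2/3 IT neurons, and simulated 1.5-fold changes were recovered for 12 of 50 genes in microglia and 15 of 50 in L2/3 IT neurons. In astrocytes, with library medians of 5700 to 8288, it was 5 of 50, so recovery did not follow depth alone.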

Other observations

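The test of depth on the cholesterol list and equal nuclei per fine cluster were chosen only after the results had been seen, as were the genes named here. Beyond the genes described so far, astrocytes of pregnant mice had more Etnppl, which breaks down phosphoethanolamine (141 ± 33.0 to 262 ± 37.7 CPM, SD, n = 2 each), and more Foxo3, a transcription factor restrained by insulin signalling (log2 fold change 0.85), and Slc24a4, a sodium-calcium exchanger (2.37). They had less Sat1, which acetylates polyamines (461 ± 23.5 to 301.3 ± 1.16 CPM), less Bcl6, a transcriptional repressor (84.0 ± 9.78 to 44.2 ± 10.0 CPM), and less Kcnk2, a potassium channel (-0.75). All passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 8.09e-06 for Etnppl to 0.0294 for Kcnk2. Of these 6 genes only Etnppl passed with equal nuclei per fine cluster, and 0 passed with DESeq2. With equal nuclei per fine cluster the log2 fold changes were 0.87 for Foxo3, 2.27 for Slc24a4, -0.53 for Sat1, -0.995 for Bcl6 and -1.07 for Kcnk2.

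The lower cholesterol synthesis transcripts in astrocytes may be a response to pregnancy, as a hypothesis found and tested on the same data, and it is not shown to be particular to astrocytes, since the list's median was also -0.17 in oligodendrocytes and -0.19 in precursors (adjusted p 0.0641 and 0.0628 by camera), against 0.23 in microglia. Dilution by free RNA from neurons is argued against, because genes more than 4-fold higher in astrocytes than in excitatory neurons had a median log2 fold change of -0.052. Lower depth per astrocyte is argued against too, because without non-pregnant replicate 2, where the depth ratio was 1.05, the list's median was -0.59. The call rests on the preset correlation of camera (p = 0.105 with an estimated correlation), and a different dissected area stays open, since it was not tested for astrocytes.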
